A study of Mus musculus with 6 samples.

How the data were processed

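RNA sequencing was done on dissected dentate neuroepithelium, the part of the hippocampal ventricular wall from which the dentate gyrus forms, of mice labelled embryonic day 14. The 6 libraries were grouped by the genotype in their titles into wild type, heterozygous for a floxed Sox11 allele and homozygous for it, with 2 libraries each. Per the labels, poly(A) RNA was selected with oligo(dT) and made into libraries with a TruSeq kit for paired-end sequencing. No Cre driver is named in the sources used here, and nothing there says that the libraries came from separate embryos or litters.

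The values used were TPM, deposited by the authors as 1 table of 35274 genes with versioned Ensembl identifiers and symbols. TPM is an abundance corrected for transcript length and scaled so that each library sums to 1000000. Per the labels' design text, reads were aligned to mm10 with TopHat 2.0.11 and analysed with Cufflinks 2.2.1 and a RefSeq annotation. The submitters' processing notes instead name FastQC and RSEM with the builds mm10 and GRCm38, and no versions. The annotation release and the handling of reads that match several genes are not given in the sources used here. A TPM table keeps no read depth, so the depth of each library is unknown and no counting interval or detection floor was computed. Because TPM values share a fixed total, a very abundant transcript in some libraries lowers all others there.

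Gene positions and types came from GENCODE vM21 on GRCm38, matched by Ensembl identifier without version, which found 34845 of the 35274 rows. Of the table's rows, 21859 were protein-coding, 12461 were pseudogenes and 22 were of the lincRNA, antisense, miRNA and snoRNA types, so long non-coding RNA was hardly covered. Near-identical copies of ribosomal genes among the transcripts were found with BLAST 2.17.0. No per-sample column of the table was left out.

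Values were used as log2(TPM + 1), a scale that understates the change of low genes, and genes with a mean of at least 1 TPM over the 6 libraries were tested (14518 genes). All 6 libraries entered limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with a term per genotype, 3 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The 3 pairwise comparisons, the departure of heterozygous libraries from the midpoint of the other genotypes, and a linear trend over 0, 1 and 2 floxed alleles were tested. Every adjusted p of a gene below comes from limma. Exact tests of 2 against 2 libraries cannot give a two-sided p below 0.33, and 2 against 4 cannot go below 0.067. Chance values given below for unadjusted p and for non-overlap are averages. Genes vary together, so observed values can lie far from them in either direction without an effect. Errors of TPM means are SD over 2 libraries, and errors of log2 fold changes are limma's SE.

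Gene lists, 24 in number, were written before the data were examined: cell types of the embryonic hippocampus and its surroundings, cell cycle phases, polarity, axon guidance, stress responses, blood, mitochondrial and sex-linked RNA. The sex-linked list had fewer than 5 measured genes and was not tested. The other 23 were tested with limma's camera against all other genes, with a preset inter-gene correlation of 0.01 and adjustment over the 23 lists. The test was repeated with an estimated correlation. In addition fry, which asks whether a list changed at all and not whether it changed more than other genes, was run on the same lists. Members of each list were also counted when adjusted over the list alone. Some lists share genes, most of all the dentate granule lineage list, so their calls are not separate results. A list of 97 motile cilia genes and another of 40 genes of the mature forebrain were written after the data had been seen and were tested as a separate family.

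Named genes followed a rule also set before the data were examined. Sox11, Sox4 and Sox12 were always named. For each pairwise comparison, the 12 largest changes in each direction were taken among genes past the threshold with a mean of at least 5 TPM and no overlap between the libraries of both genotypes, and places left over were filled by the smallest unadjusted p and are said not to pass. Symbols made of Gm, LOC, AC, BC, AK, AI, AU or AW and digits or ending in Rik, and mitochondrial transcripts, were skipped, and up to 4 members of a list with the smallest p were named. Where a count of calls was small, all its genes are named, some outside this rule and after their values were seen.

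The gene test was tried on simulated data built on these libraries with 50 genes changed at each of 4 sizes. For homozygous against wild type, over 14518 genes, it recovered 78% of 50 genes changed 2-fold, 100% of those changed 4-fold and 98% of those changed 16-fold, with 17 false calls among 205. For heterozygous against wild type, 10% of genes changed 1.41-fold and 80% of genes changed 2-fold were recovered, with 18 false calls among 156. There were 9 false calls among 151 between floxed genotypes and 16 among 206 for the trend. In each of these comparisons the share of false calls lay above the adjusted p threshold of 0.05. For the midpoint, from which no simulated gene departed, 0 genes were called. In homozygous against wild type, all 10 simulated lists shifted by 0.5 on the log2 scale were called, and 0 of 10 unshifted ones, by camera with either correlation and by fry. These simulations assume independent genes that vary as limma estimated, so recovery in the real data may be lower. Sox11 changed by -1.56 on the log2 scale in heterozygous libraries and did not pass.

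Alternatives tried were a pseudocount of 0.1, no filter on low values, a mean of at least 5 TPM, rescaling by trimmed means of M-values (TMM, own implementation), the replicate number as a block, and leaving out each library in turn. Gene counts and the genes called were also recomputed with only the 2 genotypes compared (pairwise comparisons), without the intensity trend and at an adjusted p of 0.1. A run without the 2 libraries with the most Ttr, which are replicate 1 of each floxed genotype, was added after the data had been seen, as was a correlation of fold changes with a different wild type control for each floxed genotype. Where a run leaves a genotype with 1 library, that library is assumed to vary like the others. Without the 2 libraries with the most Ttr, the spread comes from the 2 wild type libraries alone. Counts and adjusted p of that run are therefore not comparable with those of the main run. Figures were drawn with matplotlib 3.10.9.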

Results

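Transcript levels were compared between wild type dentate neuroepithelium and tissue carrying 1 or 2 floxed alleles of Sox11, a SoxC transcription factor gene active in newborn neurons. The labels call the 2 floxed genotypes haplodeficient and homodeficient. The series title names progenitor polarity and mossy fibre projections in the hippocampus as its interest. Each genotype had 2 libraries, and 18722 to 19408 genes per library were above 0 TPM. Nothing in the labels says that libraries came from separate embryos, so p-values measure the spread between these libraries, which may be technical. Replicates correlated at r = 0.985 in wild type, 0.970 in heterozygous and 0.979 in homozygous libraries across genes, which are not independent replicates. The first principal component held 56.5% of the variance, with wild type libraries at -41.2 and -34.5, heterozygous ones at 34.2 and -1.61, and homozygous ones at 27.3 and 15.7. Genes of mature brain were present in every library labelled embryonic day 14. Gfap, the intermediate filament of astrocytes, lay between 268 and 576 TPM, and Camk2a, a synaptic kinase of excitatory neurons, between 121 and 496 TPM.

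Sox11 (ENSMUSG00000063632.6) is a gene of 1 exon on the minus strand of chromosome 12, from 27334264 to 27342574 on GRCm38. It stood at 161 ± 43.7 TPM in wild type, 53.1 ± 4.26 in heterozygous and 5.14 ± 0.120 in homozygous libraries (SD, n = 2 each), so its level followed the labelled genotype in all 6 libraries. Against wild type, Sox11 fell by 4.69 on the log2 scale in homozygous libraries (SE 0.19, limma adjusted p = 0.00082). Between heterozygous and homozygous libraries it fell by 3.14 (SE 0.19, limma adjusted p = 0.0073). The heterozygous difference from wild type was -1.56 (SE 0.19) and did not pass (limma adjusted p = 0.105). It passed with a pseudocount of 0.1 (limma adjusted p = 0.033). The difference was -1.48 without heterozygous replicate 2 and -1.64 without the 2 libraries with the most Ttr, a marker of choroid plexus. Over settings that left no genotype with 1 library, its limma adjusted p ran from 0.033 to 0.33. The difference between both floxed genotypes missed the threshold with no filter on low values (limma adjusted p = 0.085) and with eBayes without a trend (limma adjusted p = 0.067). Over the same settings its limma adjusted p ran from 0.0047 to 0.085. It also missed the threshold without homozygous replicate 1, where it was -3.16. The related SoxC genes did not pass in any pairwise comparison. Sox4 stood at 256 ± 58.2, 217 ± 22.7 and 202 ± 14.7 TPM in wild type, heterozygous and homozygous libraries, and Sox12 at 63.1 ± 1.17, 56.1 ± 2.59 and 60.1 ± 8.20 TPM (SD, n = 2 each).

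**Figure D1:**
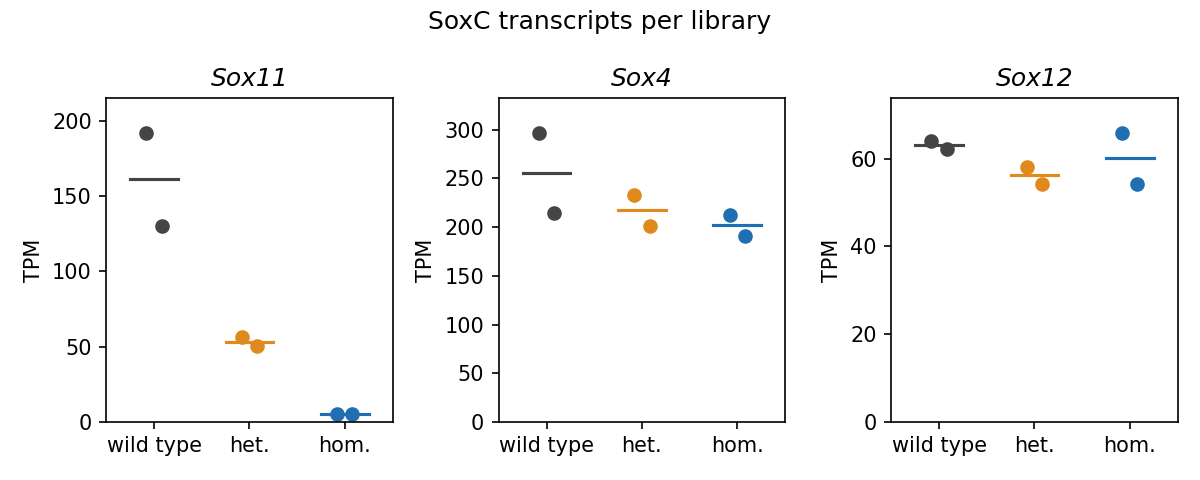
TPM of Sox11, Sox4 and Sox12 (y axes, from 0) by genotype, with a point per library and a bar at the mean of 2 libraries. Sox11 stands at 161 TPM in wild type and at 53.1 and 5.14 TPM with 1 and 2 floxed alleles, while Sox4 and Sox12 did not pass the test in any pairwise comparison.

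Heterozygous tissue was first compared with wild type for single genes. Ccdc153, named for its coiled coils, rose from 0.295 ± 0.417 to 46.7 ± 13.8 TPM (log2 fold change 5.21, SE 0.29, limma adjusted p = 0.0030). Tmem212, a membrane protein gene, was listed at 0 in both wild type libraries and at 21.1 and 11.2 TPM in heterozygous ones (limma adjusted p = 0.012). Myo7a, an unconventional myosin, rose from 0.85 and 0.55 TPM to 21.3 and 14.1 TPM (log2 fold change 3.44, SE 0.32, limma adjusted p = 0.0498). The other 9 higher genes of the naming rule did not pass. They are Dynlrb2, Meig1, Tctex1d4, Fam183b, Rsph4a, Dnali1, Ppp1r32, Lrrc74b and Dmkn, with log2 fold changes of 2.77 or more and limma adjusted p from 0.105 to 0.124. Of the 12 higher genes named, 8 belong to the motile cilia list that was written after the data had been seen. Among lower genes, only Rps13-ps1, a pseudogene of the ribosomal gene Rps13, passed, from 1133 ± 90.2 to 10.6 ± 1.30 TPM (limma adjusted p = 0.00047). The next on the rule were Sox11, Islr2, Epha4, Klhl35, Dpf3, Crabp1, Tspan18, Auts2, Rbfox1, Zbtb20 and Nrp2, none of which passed (limma adjusted p from 0.105 to 0.172). Islr2, a neuronal surface protein, stood at 862 and 700.5 TPM in wild type and at 465 and 454 TPM in heterozygous libraries. Epha4, an ephrin receptor, stood at 249 ± 9.12 and 154 ± 14.8 TPM, and the neuropilin gene Nrp2 at 165 ± 5.43 and 104 ± 17.2 TPM (SD, n = 2 each).

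Of 14518 genes, 4 rose and 1 fell with limma at an adjusted p of 0.05, and 2040 had an unadjusted p under 0.05, where chance gives 726. The fourth higher gene was Gm6472, a pseudogene of the ribosomal gene Rps7 on chromosome X (limma adjusted p = 0.0017), which rose from 0.990 ± 1.36 to 796 ± 40.2 TPM. Gm6472 matches Rps7 over 651 bases at 99.39% identity and Rps13-ps1 matches Rps13 over 522 bases at 99.62%, so the levels of these pseudogenes and of their parent genes are uncertain. Libraries of both genotypes did not overlap for 46.0% of genes, where chance gives 33.3%. Both chance values are averages, and genes that vary together can move the observed values far from them, so neither excess was tested. The count of 5 genes was 49 with a pseudocount of 0.1 and 1 with no filter, 3 without either wild type library, 25 without heterozygous replicate 1, 397 without heterozygous replicate 2, and 152 without the 2 libraries with the most Ttr. Myo7a (limma adjusted p = 0.51 and 0.22) and Tmem212 (0.33 and 0.18) lost their calls without wild type replicate 1 and 2, Ccdc153 without wild type replicate 2 (0.065), and with no filter only Rps13-ps1 kept its call, Ccdc153 standing at 0.064 and Gm6472 at 0.052. Myo7a also lost its call with a mean of at least 5 TPM (0.051), with TMM rescaling (0.076), with the replicate block (0.054) and with eBayes without a trend (0.14).

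Among lists for heterozygous against wild type, the immune and glial lists stood higher. The microglia and macrophage list was called higher (camera adjusted p = 1.0e-12, 0.74 with an estimated correlation), with all 25 members above wild type and 14 rising when adjusted over the list alone. Csf1r, the receptor that microglia need to survive, went from 15.6 ± 1.39 to 29.3 ± 5.91 TPM, Tyrobp from 25.9 ± 3.49 to 55.7 ± 17.9 TPM and C1qb from 34.2 ± 2.02 to 69.3 ± 22.8 TPM. Oligodendrocyte precursor and astrocyte genes were called higher (camera adjusted p = 3.2e-05, 0.74 with an estimated correlation, 2 of 20 rising when adjusted over the list alone), among them Apoe, a lipid carrier of astrocytes, at 969 ± 195 and 1833 ± 237 TPM, and Olig1 at 97.3 ± 30.5 and 166 ± 1.02 TPM. The choroid plexus list was called higher (camera adjusted p = 2.0e-08, 0.74 with an estimated correlation, 24 of 25 members above wild type), with 1 member, Foxj1, the regulator of motile cilia, rising when adjusted over the list alone. Ttr, the main secreted protein of choroid plexus, differed widely within genotypes, at 3.07 and 2.04 TPM in wild type, 11259 and 4.44 in heterozygous and 6421 and 184 in homozygous libraries. Radial glia and neural stem cell genes had a median log2 fold change of 0.20, or 0.014 without heterozygous replicate 1 (camera adjusted p = 0.0037, 0.74 with an estimated correlation), with 0 of 30 passing over the list alone.

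Neuronal and proliferation lists were called lower in heterozygous libraries, in which the microglia list stood 0.85 and 0.38 above wild type on the log2 scale. The dentate granule lineage list was called lower (camera adjusted p = 0.00048, 0.74 with an estimated correlation), with 10 of 23 members falling when adjusted over the list alone. This list shares 12 of its 24 genes with other lists. Its examples are Zbtb20, a hippocampal zinc-finger gene (148.5 ± 17.7 to 98.3 ± 3.27 TPM), Prox1, the granule cell determinant (143 ± 45.5 to 68.1 ± 19.6 TPM) and Draxin, a guidance cue (110 ± 17.8 to 69.7 ± 4.29 TPM). In axon guidance, 8 of 74 members fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.00063, 0.74 with an estimated correlation), Epha4, Nrp2, Sema4c and Ephb2 having the smallest p. The pan-neuronal list was called lower (camera adjusted p = 0.00040, 0.74 with an estimated correlation), with 38 of 44 members below wild type and Rbfox1 alone falling over the list alone. Intermediate progenitors (camera adjusted p = 0.0048, Sstr2 falling over the list alone) and Cajal-Retzius cells (camera adjusted p = 0.010) were also called lower, both at 0.74 with an estimated correlation. Their medians of -0.34 and -0.47 depended on single libraries and were -0.02 and -0.09 without wild type replicate 1. S phase (camera adjusted p = 1.9e-06, 0.74 with an estimated correlation, 54 of 54 members lower) and G2 and M phase (camera adjusted p = 0.012, 0.86 with an estimated correlation, 54 of 59 lower) were called lower with 0 members passing over the list alone.

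In total 11 of 23 lists were called, 4 higher and 7 lower, while 0 members of any list passed over all genes. With an estimated correlation 0 lists were called (lowest adjusted p = 0.74 with an estimated correlation), and fry, which tests a list against no change, called 0 (lowest adjusted p = 0.41). Leaving out wild type replicate 1 ended the calls of intermediate progenitors (adjusted p = 0.33) and Cajal-Retzius cells (0.085) and turned that of G2 and M phase (0.24). Leaving out wild type replicate 2 ended those of radial glia (adjusted p = 0.15), pan-neuronal genes (0.49) and axon guidance (0.068), leaving out heterozygous replicate 1 those of radial glia (0.11) and pan-neuronal genes (0.28), and leaving out heterozygous replicate 2 that of G2 and M phase (0.67). Without the 2 libraries with the most Ttr, radial glia (0.28) and pan-neuronal genes (0.39) were not called. The apical-basal and planar polarity and adherens junction list was not called (camera adjusted p = 0.34, median -0.09, 0 of 64 passing over the list alone). Of the polarity members, Afdn, which ties adherens junctions to actin, stood at 122 ± 11.5 and 88.2 ± 3.44 TPM. Also not called were pyramidal and other glutamatergic neurons (camera adjusted p = 0.67; the mean of 0.07 lay above 0, the median and test below; Zbtb20 among 5 falling and 1 rising over the list alone), the cortical hem (0.13), the ventral GABAergic lineage (0.076), thalamus (0.68), p53 response (0.77), hypoxia (0.097; Car9 and Egln3 rising over the list alone), immediate early genes (0.097), endothelium (0.073), erythroid cells (0.66), meninges (0.13) and mitochondrial messenger RNA (0.66). For p53 response, immediate early and erythroid genes the median lay below 0 and the mean and test above, and for mitochondrial messenger RNA the mean alone lay below 0.

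**Figure D2:**
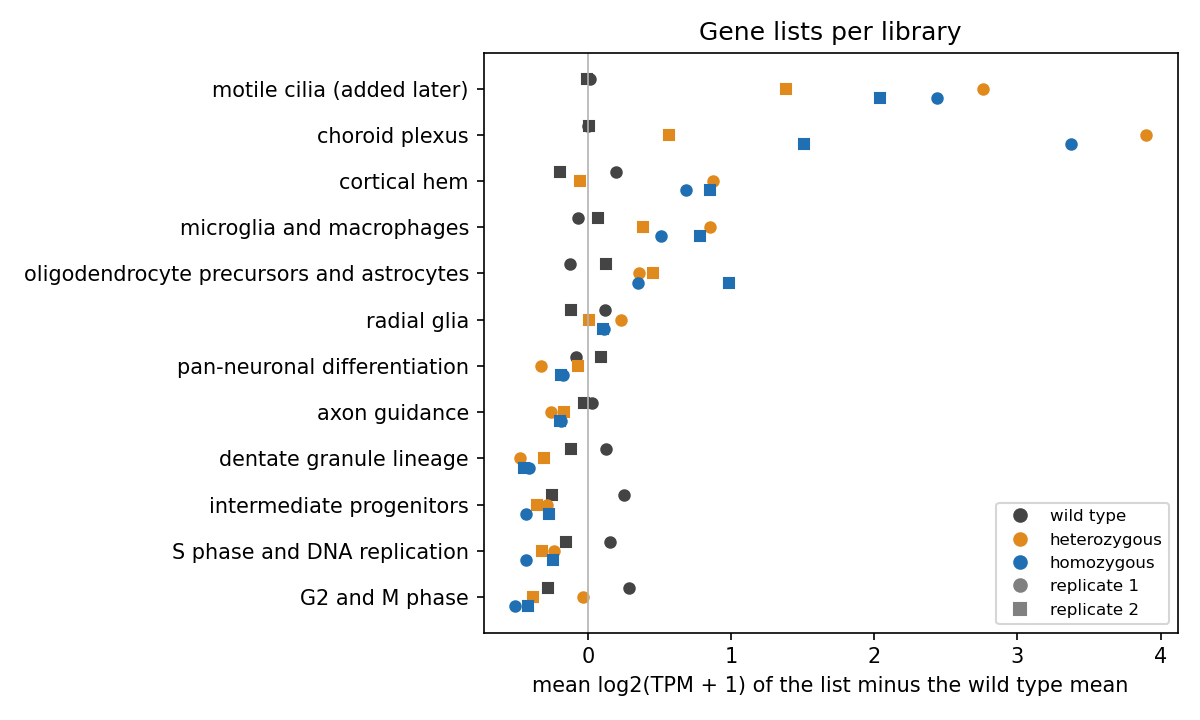
Mean log2(TPM + 1) of each list minus the mean of both wild type libraries (x axis), with a point per library, circles for replicate 1 and squares for replicate 2. Choroid plexus genes stand at 3.90 and 0.56 in the 2 heterozygous libraries and at 3.38 and 1.51 in the homozygous ones, and microglia genes at 0.85, 0.38, 0.51 and 0.78.

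Homozygous tissue was compared with wild type in the same way. Ccdc153 rose to 62.6 ± 9.31 TPM (log2 fold change 5.65, SE 0.29, limma adjusted p = 0.0018) and Tmem212, listed at 0 in wild type, stood at 21.9 and 19.9 TPM (limma adjusted p = 0.0065). The other higher genes by rule were Dynlrb2, Lrrc74b, Meig1, Dmkn, Tctex1d4, Rps2-ps10, Myo7a, Fam183b, Dnali1 and Rsph4a, none of which passed (limma adjusted p = 0.061 for each). Dynlrb2, a dynein light chain, stood at 0.435 ± 0.304 TPM in wild type and 64.5 ± 23.0 in homozygous libraries. Lower genes that passed were Sox11 and Rps7, a ribosomal protein gene on chromosome 12 from 28630854 to 28635953, which fell from 1939 ± 27.5 to 1012 ± 3.44 TPM (-0.94, SE 0.09, limma adjusted p = 0.046). The next lower genes by rule were CT030170.3, Draxin, Sema4c, Rnf152, Dcx, Islr2, Gpc2, Tubb5, Mtss1 and Tmem44, with limma adjusted p from 0.050 to 0.061, none passing. Among them Dcx, a microtubule protein of migrating neurons, stood at 390 ± 2.30 TPM in wild type and 212 ± 33.8 TPM in homozygous libraries. Tubb5, a tubulin, stood at 1871 and 1808 TPM in wild type and 1181 and 1193 TPM in homozygous libraries, and Sema4c, a semaphorin, at 57.8 and 46.4 TPM in wild type and 25.5 and 24.5 TPM in homozygous libraries.

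In all, 3 genes rose and 3 fell with limma, and 2635 had an unadjusted p under 0.05 against 726 by chance. The third higher gene was Gm6472, at 1628 ± 38.7 TPM (limma adjusted p = 0.00082), whose level is uncertain since it is nearly identical to Rps7. The third lower gene, AC166358.6, is a pseudogene on chromosome 12 from 22584129 to 22587635 that fell from 15.3 ± 0.771 to 3.92 ± 0.0141 TPM (limma adjusted p = 0.046). The split between higher and lower genes was 3 and 2 after TMM rescaling. It was 117 and 32 with a pseudocount of 0.1, 161 and 122 with the replicate block, and 333 and 60 with these 2 genotypes only. The other large counts below also held mostly higher genes. Libraries did not overlap for 54.3% of genes, where chance gives 33.3%. Here too, genes that vary together limit what these excesses show. At an adjusted p of 0.1, 256 genes were called, 160 higher and 96 lower, and 37 of the higher ones belong to the motile cilia list made after the data had been seen. The count of 6 was 149 with a pseudocount of 0.1, 3 with no filter, 3 without wild type replicate 1, 391 and 397 without heterozygous replicates 1 and 2, 393 with the libraries of these 2 genotypes only, and 491 without the 2 libraries with the most Ttr. Tmem212, Rps7 and AC166358.6 lost their calls without either wild type library and without either homozygous library, Rps7 also with TMM rescaling (limma adjusted p = 0.077) and with eBayes without a trend (0.12), and all 3 with no filter (Tmem212 at 0.093, Rps7 and AC166358.6 at 0.17). Over settings that left no genotype with 1 library, the limma adjusted p of Rps7 ran from 0.0079 to 0.17 and that of Tmem212 from 0.0011 to 0.093.

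Among the lists for homozygous against wild type, those called lower held neuronal and cell cycle genes. The dentate granule lineage was called lower (camera adjusted p = 0.00032, 0.59 with an estimated correlation), with 11 of 23 members falling when adjusted over the list alone, among them Draxin, Dcx, Zbtb20 and Calb2. Of the 24 genes listed, 12 are also in other lists. Axon guidance genes were called lower (camera adjusted p = 0.0029, 0.59 with an estimated correlation), with 16 of 74 falling and 2 rising over the list alone. Cntn2, an adhesion molecule of axons, went from 134 ± 8.63 to 66.5 ± 8.79 TPM, while Ntrk2, the receptor of BDNF, went from 73.6 ± 4.29 to 109.5 ± 5.70 TPM. Pan-neuronal genes were called lower (camera adjusted p = 0.00094, 0.59 with an estimated correlation), with 7 of 44 falling over the list alone, among them Tubb3, the neuronal tubulin, from 1600 ± 182 to 984 ± 26.5 TPM. S phase genes (camera adjusted p = 1.3e-08, 54 of 54 below wild type) and G2 and M phase genes (camera adjusted p = 6.3e-09, 58 of 59 below) were called lower, both at 0.59 with an estimated correlation, with 0 members of either list passing over the list alone. Mcm7, a part of the replicative helicase, stood at 87.1 ± 19.7 and 54.5 ± 2.62 TPM. Relative to the wild type mean, G2 and M phase genes lay at 0.28 and -0.28 in wild type and at -0.51 and -0.42 in homozygous libraries. Their median of -0.46 ran from -0.82 to -0.17 when single libraries were left out. Their estimated inter-gene correlation was 0.82 against the preset 0.01. Intermediate progenitors (camera adjusted p = 0.00094, 2 of 19 falling over the list alone) and Cajal-Retzius cells (camera adjusted p = 0.014, 2 of 18 falling over the list alone) completed the lower lists, both at 0.59 with an estimated correlation.

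Higher lists in homozygous libraries were again glial, immune and choroid. Microglia genes were called higher (camera adjusted p = 5.3e-10, 0.59 with an estimated correlation), with 24 of 25 members above wild type and 11 rising over the list alone, Csf1r reaching 33.2 ± 0.453 TPM. Oligodendrocyte precursor and astrocyte genes were called higher (camera adjusted p = 2.3e-07, 0.59 with an estimated correlation, 5 of 20 rising over the list alone), with Apoe at 2200 ± 120 TPM and Clu at 286 ± 32.6 against 90.2 ± 9.14 TPM. Choroid plexus genes were called higher (camera adjusted p = 4.2e-07, 0.59 with an estimated correlation, Foxj1 rising over the list alone), in libraries whose Ttr levels were 6421 and 184 TPM. The cortical hem list, which holds Wnt and BMP signals, was called (camera adjusted p = 0.0011, 0.59 with an estimated correlation, 24 of 29 members higher, 0 passing over the list alone), and its members with the smallest p include Msx1 (3.17 ± 0.820 to 23.2 ± 7.84 TPM) and Bmp4 (1.02 ± 0.226 to 5.62 ± 0.00707 TPM). Hypoxia and glycolysis genes were called (camera adjusted p = 0.0011, 0.59 with an estimated correlation), Car9 rising and Pfkfb3 falling over the list alone. Immediate early genes (camera adjusted p = 0.033), meninges (0.045) and radial glia (0.032) were also called higher, with Hspb1, a small heat shock protein, rising over the immediate early list alone. With an estimated correlation these 3 stood at 0.59, 0.82 and 0.64.

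Here 15 of 23 lists were called, 8 higher and 7 lower, with 0 members passing over all genes. With an estimated correlation 0 lists were called (lowest adjusted p = 0.59 with an estimated correlation), and fry, against no change, called 0 (lowest adjusted p = 0.30). Leaving out wild type replicate 1 ended the calls of intermediate progenitors (adjusted p = 0.11), Cajal-Retzius cells (0.15), hypoxia (0.11) and immediate early genes (0.14), and leaving out wild type replicate 2 those of radial glia (0.33), pan-neuronal genes (0.39), the cortical hem (0.11), axon guidance (0.11) and meninges (0.44). Without homozygous replicate 1 the calls of radial glia (0.11) and Cajal-Retzius cells (0.065) ended, and without homozygous replicate 2 that of immediate early genes (0.20) ended and that of meninges turned lower (0.0026). Without either heterozygous library, immediate early genes (0.080) and meninges (0.075) were no longer called, and without the 2 libraries with the most Ttr radial glia (0.24) were not. Meninges also lost their call with a pseudocount of 0.1 (0.076), no filter (0.055), a mean of at least 5 TPM (0.072) and TMM rescaling (0.15), and immediate early genes with the last 2 settings (0.056 and 0.058). The polarity and adherens junction list was not called (camera adjusted p = 0.46, median -0.04, 0 of 64 passing over the list alone), and its smallest p belonged to Ctnna2, an alpha-catenin of neurons, at 116 ± 6.84 and 82.1 ± 2.58 TPM. Pyramidal neurons (camera adjusted p = 0.067), the GABAergic lineage (0.46; median below 0, mean and test above), thalamus (0.38), p53 response (0.57), endothelium (0.25; Slco1c1, a transporter of brain vessels, rising over the list alone), erythroid cells (0.46) and mitochondrial messenger RNA (0.18) were not called either.

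Homozygous and heterozygous libraries were then compared directly, to ask what the second floxed allele added. Sox11 was the lower gene that passed, and Rps13-ps1 the higher one, from 10.6 ± 1.30 to 1003 ± 367 TPM (limma adjusted p = 0.00059). Rps13-ps1 is nearly identical to Rps13, so this value is uncertain. The remaining higher genes of the rule were Cpeb1, Hap1, Coa4, Rnf112, Tdo2, Pfkp, Atg16l2, Plekhb1, S100a4, Cpt1c and Nrbp2, and the lower ones included Rps7, CT030170.3, Dctn5, Gpr21, Serpini1, Dcx, Gpc2, Myl6b, Ube2d1 and Carhsp1. None of these passed (limma adjusted p = 0.30 for Rps7 and 1.0 for the rest). Dcx stood at 290 ± 8.56 TPM in heterozygous and 212 ± 33.8 in homozygous libraries. The unadjusted p lay under 0.05 for 297 genes, fewer than the 726 chance gives, and 29.1% of genes did not overlap, where chance gives 33.3%. The count of 2 genes was 1 with no filter and without homozygous replicate 1, 1 without an intensity trend, 5 without homozygous replicate 2 and 12 without the 2 libraries with the most Ttr.

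Among lists, the mitotic genes stood apart in this comparison. G2 and M phase genes were called lower in homozygous than in heterozygous libraries (camera adjusted p = 8.7e-12, 0.99 with an estimated correlation, 55 of 59 members lower). Their median of -0.29 depended on heterozygous replicate 1, without which it was -0.096 (camera adjusted p = 0.0019), and it was -0.040 without the 2 libraries with the most Ttr (camera adjusted p = 0.029). S phase (camera adjusted p = 0.020) and pyramidal neuron genes (0.010) were also called lower, both at 0.99 with an estimated correlation. Lists called higher were the cortical hem (camera adjusted p = 0.00080, 27 of 29 members higher), hypoxia (0.018) and oligodendrocyte precursors and astrocytes (0.018), each at 0.99 with an estimated correlation. Of these 6 calls, 0 held with an estimated correlation, fry called 0 lists against no change (lowest adjusted p = 0.97), and no member of any list passed over the list alone. With the preset correlation, only G2 and M phase kept its call when any single library was left out, with medians from -0.46 to -0.096. Without heterozygous replicate 1 S phase (adjusted p = 0.053), hypoxia (0.20) and glial genes (0.27) lost theirs, and without heterozygous replicate 2 pyramidal neurons (0.071), the hem (0.70) and S phase (0.13) did. Leaving out homozygous replicate 1 turned S phase (0.80), and leaving out homozygous replicate 2 ended pyramidal neurons (0.68), the hem (0.27) and hypoxia (0.27) and turned glial genes (0.59). The count of called lists rose to 10 without homozygous replicate 1 and to 13 without the 2 libraries with the most Ttr, where S phase (0.97) and hypoxia (0.13) were not called. Not called were radial glia (camera adjusted p = 0.48), intermediate progenitors (0.26), the granule lineage (0.25), pan-neuronal genes (0.64; median and mean above 0, test below), choroid plexus (0.97), Cajal-Retzius cells (0.92), the GABAergic lineage (0.26), thalamus (0.26), polarity (0.79), axon guidance (0.97), p53 response (0.26), immediate early genes (0.26), endothelium (0.67), microglia (0.97), erythroid cells (0.85), meninges (0.35) and mitochondrial messenger RNA (0.25). For choroid plexus, Cajal-Retzius and axon guidance genes the median and mean also lay above 0 and the test below.

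A linear trend over 0, 1 and 2 floxed alleles was passed by 2 genes, both falling. Sox11 fell by 2.35 per allele on the log2 scale (SE 0.19, limma adjusted p = 0.027). The chromosome 12 pseudogene AC166358.6 fell by 0.86 per allele (SE 0.07, limma adjusted p = 0.027), at 15.3 ± 0.771, 7.70 ± 0.276 and 3.92 ± 0.0141 TPM with 0, 1 and 2 floxed alleles (SD, n = 2 each). No gene rose with the trend in the main run, where 2755 genes had an unadjusted p under 0.05 (1246 rising and 1509 falling) against 726 by chance. The larger counts below were mostly of rising genes. The count was 0 with no filter, 0 without wild type replicate 1, heterozygous replicate 2 or either homozygous library, 1 without wild type replicate 2, 1 without an intensity trend (Sox11 missing it at 0.095), 554 without heterozygous replicate 1, and 252 without the 2 libraries with the most Ttr. Departure from the midpoint was passed by 1 gene, Rps13-ps1, which lay 6.50 below it in heterozygous libraries (SE 0.20, limma adjusted p = 0.00020). Here 591 genes had an unadjusted p under 0.05 (286 above and 305 below the midpoint), where chance gives 726. Without heterozygous replicate 2, unlike in the main run, most calls lay above the midpoint. The count was 2 with a pseudocount of 0.1, 2 without either wild type library, heterozygous replicate 1 or homozygous replicate 1, 4 without homozygous replicate 2, 56 without heterozygous replicate 2 and 11 without the 2 libraries with the most Ttr.

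**Figure D3:**
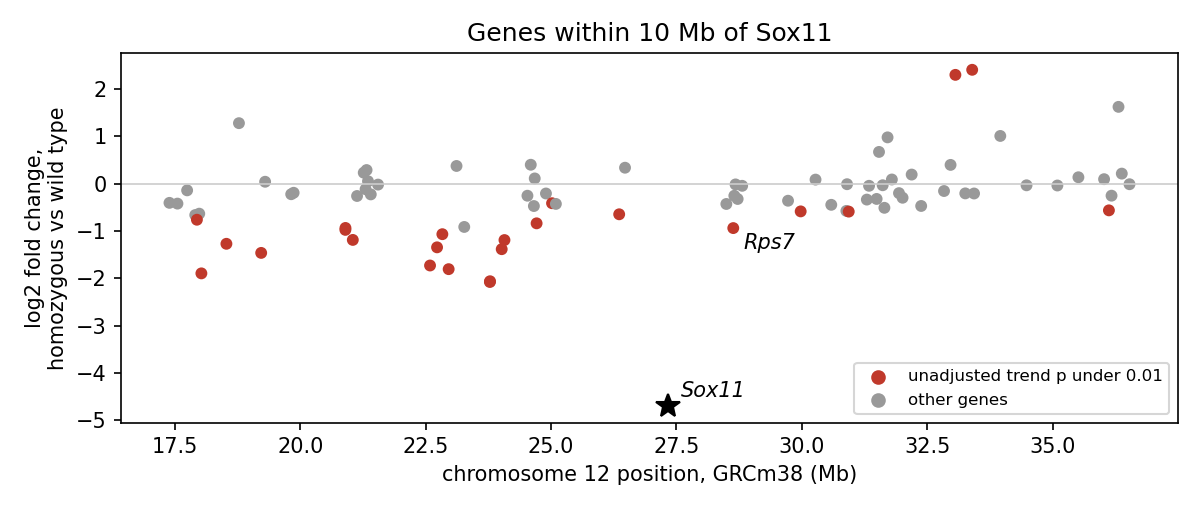
Log2 fold change of homozygous against wild type libraries (y axis) for each tested gene within 10 Mb of Sox11 by its position on chromosome 12 in Mb (x axis, GRCm38), with genes of an unadjusted trend p under 0.01 in red. Sox11 lies at -4.69, and 22 of the 24 red genes lie lower with more floxed alleles.

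Both floxed genotypes moved alike relative to wild type. Across 14518 genes, which are not independent replicates, their log2 fold changes correlated at r = 0.896, where libraries without any effect that share these wild type controls gave 0.497 ± 0.019 (SD of 100 simulations). The covariance was 0.216 against 0.0287 in the simulations, and 83.1% of genes had the same sign against 66.7%. The simulations drew each gene independently, while the choroid plexus list, for example, had an estimated inter-gene correlation of 0.92. Their SD is therefore too small to judge the excess. With a different wild type library as control for each floxed genotype, a run added after the data had been seen, the correlation was 0.706 and 0.670 in the 2 possible pairings. A difference common to both wild type libraries, of whatever cause, would remain in these values. The correlation was 0.786 and 0.840 without heterozygous replicates 1 and 2, 0.807 without homozygous replicate 1 and 0.762 without the 2 libraries with the most Ttr.

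**Figure D4:**
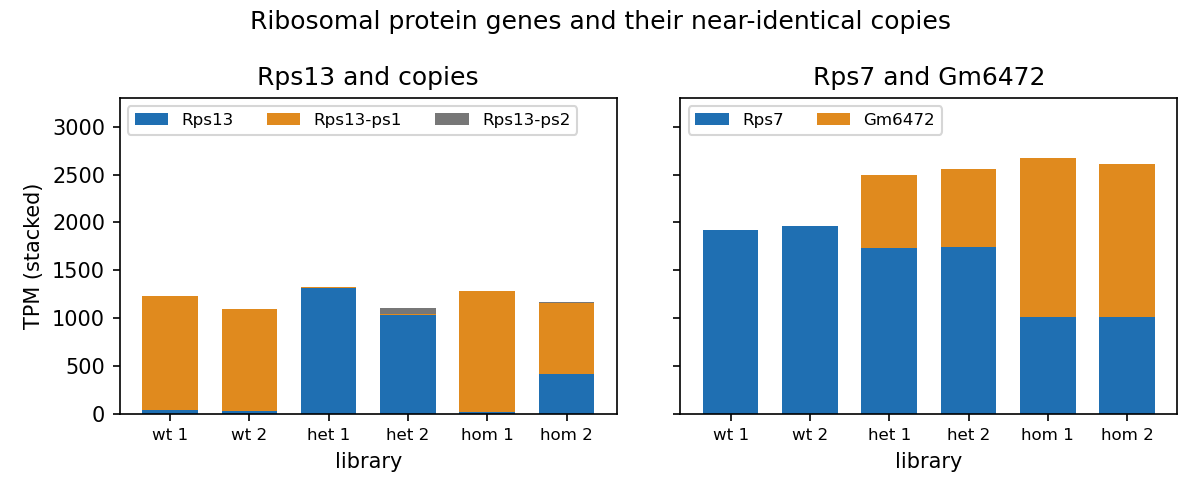
TPM (y axis, stacked bars from 0) in each library of Rps13 with its pseudogenes (left) and of Rps7 with Gm6472 (right). The Rps13 sum lies between 1093 and 1325 TPM in all libraries while Rps13 alone ranges from 20.9 to 1308 TPM.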

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

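The run without the 2 libraries with the most Ttr and that with separate wild type controls were chosen after seeing the data, and the other settings before. Agreement in the tally of genes below was partly fixed in advance. Genes named for not overlapping cannot change direction when 1 library is left out, and several settings leave the fold change as it was. A result that passed in neither run also counts as kept. Of 2627 recomputed values for 220 results on named genes, 2348 kept their direction and their side of the threshold, 29 no longer passed, 245 newly passed and 5 changed direction. Of 963 values for 69 list results, 738 kept both, 109 lost their call, of which 32 with an estimated correlation and 32 with fry, 49 gained one and 67 changed the direction of the test, 53 of them called in neither run. The fall of Sox11 in homozygous against wild type libraries passed in all 15 runs that tested it. Among runs that left no genotype with 1 library, its limma adjusted p ran from 0.00053 to 0.027. Where a genotype is left with 1 library, that library is assumed to vary like the others. Read depth is unknown, so its effect on low genes could not be measured. TMM rescaling moved the median of all genes by less than 0.1 on the log2 scale. The cause of a change was not tested unless named.

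With a pseudocount of 0.1, 49 genes changed in heterozygous and 149 in homozygous against wild type and 2 departed from the midpoint, while Sox11 passed in heterozygous libraries at -1.57. With no filter, which tests more genes, the counts were 1, 3 and, between floxed genotypes, 1, with 0 on the trend, and Sox11 no longer passed between floxed genotypes at -3.14 (nor with eBayes without a trend). With the replicate block, 9 genes changed in heterozygous and 283 in homozygous libraries, 6 followed the trend and 2 departed from the midpoint. The replicate numbers are not known to pair the libraries, and same-numbered deviations correlated across genes at only 0.21, -0.088 and 0.35. Mitochondrial messenger RNA and the mature forebrain list stood higher in replicate 2 of every genotype. With only the 2 genotypes compared, 393 genes changed in homozygous libraries, and at an adjusted p under 0.10 there were 256. With eBayes without a trend, 1 gene changed between floxed genotypes and 1 followed the trend. An estimated correlation and fry, which tests lists against no change, each called 0 lists in heterozygous, 0 in homozygous and 0 between floxed genotypes.

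Without the 2 libraries with the most Ttr, 152 genes changed in heterozygous, 491 in homozygous, 12 between floxed genotypes, 252 on the trend and 11 from the midpoint. Lists called between floxed genotypes were 13, the correlation of fold changes was 0.762, and Sox11 passed in heterozygous libraries at -1.64. In this run the spread came from the 2 wild type libraries alone, so its counts and passes are not comparable with those of the main run. The tests of the following lists changed direction there, with these medians of log2 fold change, not all of which changed sign. Heterozygous against wild type they were the hem (-0.0316) and p53 response (-0.105), and homozygous against wild type the GABAergic lineage (-0.176). Between floxed genotypes they were radial glia (0.146), choroid plexus (0.819), Cajal-Retzius cells (0.196), endothelium (0.274) and mitochondrial RNA (-0.00785), and the gene Sox12 turned to -0.000522.

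Under other settings some list tests changed direction, with these medians, all of which kept their sign. Choroid plexus between floxed genotypes did so with a pseudocount of 0.1 (0.263), a mean of at least 5 TPM (0.137), TMM rescaling (0.137), the replicate block (0.137) and fry (0.137). Axon guidance between floxed genotypes did so with no filter (0.0597), a mean of at least 5 TPM (0.0556), the replicate block (0.0584) and fry (0.0584). Cajal-Retzius cells did so there with no filter (0.0380) and fry (0.0101), and microglia with a mean of at least 5 TPM (0.0444). Heterozygous against wild type, erythroid cells turned with no filter (-0.0450), thalamus with TMM rescaling (0.137) and fry (0.0910), p53 response with fry (-0.0771) and mitochondrial RNA with fry (0.000207). Homozygous against wild type, the GABAergic lineage turned with a mean of at least 5 TPM (-0.0655). None of these tests was called in either run.

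Leaving out 1 library at a time, gene counts ran from 3 to 397 in heterozygous, 3 to 397 in homozygous, 1 to 5 between floxed genotypes, 0 to 554 on the trend and 2 to 56 from the midpoint. Lists called between floxed genotypes ran from 5 to 10 and the correlation from 0.786 to 0.919, while with separate wild type controls it was 0.706 and 0.670. Sox11 ran from -1.84 to -1.28 in heterozygous libraries and from -3.22 to -3.06 between floxed genotypes. Sox4 ran from -0.454 to 0.0121 in heterozygous libraries and from -0.209 to 0.00312 between floxed genotypes, and Sox12 from -0.212 to 0.0624 in homozygous libraries and from -0.0467 to 0.228 between floxed genotypes. For list tests that changed direction, the medians, not all of which changed sign, ran as follows. Heterozygous against wild type, pyramidal neurons ran from -0.150 to -0.0467, thalamus from 0.0179 to 0.195, G2 and M phase from -0.514 to 0.0793, p53 response from -0.117 to 0.0811, hypoxia from -0.0232 to 0.0845, erythroid cells from -0.210 to 0.293 and mitochondrial RNA from -0.222 to 0.20. Homozygous against wild type, the GABAergic lineage ran from -0.176 to 0.187, p53 response from -0.169 to 0.0122, endothelium from -0.290 to 0.428, erythroid cells from -0.279 to 0.489, meninges from -0.569 to 1.26 and mitochondrial RNA from -0.105 to 0.342.

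Between floxed genotypes, radial glia ran from -0.167 to 0.0949, the granule lineage from -0.124 to -0.0226, pan-neuronal genes from -0.121 to 0.0916, choroid plexus from -1.28 to 1.49, Cajal-Retzius cells from -0.0889 to 0.139 and the GABAergic lineage from -0.203 to 0.10. Polarity ran from -0.0671 to 0.0799, axon guidance from -0.0183 to 0.0718, S phase from -0.124 to 0.0473, immediate early genes from -0.0230 to 0.20, endothelium from -0.386 to 0.367 and microglia from -0.219 to 0.246. Erythroid cells ran from 0.0212 to 0.177, meninges from -0.620 to 1.10, oligodendrocyte precursors and astrocytes from -0.0185 to 0.349 and mitochondrial RNA from -0.0970 to 0.350.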

Other observations

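All tests in this part were chosen after the data had been seen. Motile cilia genes stood higher in both floxed genotypes. Of 94 measured genes of a list made for this purpose after the data had been seen, 94 stood higher than wild type in heterozygous and 94 in homozygous libraries, with median log2 fold changes of 1.80 and 2.04. Over all genes only 2 of the 94 rose in each genotype. Adjusted over the list alone 83 and 85 did, but these counts decide nothing, since the list was written after the data had been seen. Camera with an estimated correlation gave adjusted p of 0.20 and 0.24. Meig1 went from 2.42 ± 0.191 TPM in wild type to 33.6 ± 20.4 and 36.4 ± 9.57 TPM, and Foxj1 stood at 3 and 3.14 TPM in wild type, 131 and 26.4 in heterozygous and 90.0 and 56.7 in homozygous libraries (SD, n = 2 each). Between floxed genotypes 81 of the 94 stood higher in homozygous libraries (camera adjusted p = 0.046, 0.78 with an estimated correlation), though the list's mean levels above wild type, 2.44 and 2.04 on the log2 scale, lay between the heterozygous ones of 2.76 and 1.38.

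The mature forebrain list, also made after the data had been seen, held 39 measured genes and had a median log2 fold change of -0.02 in heterozygous (camera adjusted p = 0.32) and 0.33 in homozygous libraries (camera adjusted p = 0.00017, 0.42 with an estimated correlation). Between floxed genotypes its median was 0.32 (camera adjusted p = 1.6e-06, 0.62 with an estimated correlation), and 0 members passed over all genes or over the list alone in any comparison. Its mean level relative to the wild type mean was -0.21 and 0.21 in wild type, -0.19 and 0.31 in heterozygous and 0.11 and 0.68 in homozygous libraries. Taken as unpaired, both homozygous differences rest largely on replicate 2. Replicate 2 stood higher in every genotype, and each homozygous library exceeded the same-numbered ones of both other genotypes. However, the replicate numbers are not known to pair the libraries, and homozygous replicate 1 lay below replicate 2 of both other genotypes. The glutamate transporter gene Slc17a7 lay between 79.8 and 393 TPM, and the myelin gene Mbp between 13.9 and 76.2 TPM over the 6 libraries.

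The first pattern is the higher level of motile cilia genes in all 4 floxed libraries. Choroid plexus as the whole cause is argued against, since replicate 2 kept more of the gain of replicate 1 over wild type in cilia genes than in other choroid genes. The median share kept was 0.24 of 94 cilia and 0.011 of 22 choroid genes in heterozygous libraries, and 0.68 and 0.13 in homozygous ones, a ratio of at least 5.06, and the quartiles did not overlap. This test replaced a ratio of summed gains, which decides nothing, since its 109-fold span over the floxed libraries was 15.8-fold without heterozygous replicate 2 and 2.84-fold when Ttr was left out too. Both tests rest on the same few floxed libraries. Mean cilia levels above wild type were 2.76 and 1.38 in heterozygous and 2.44 and 2.04 in homozygous libraries (log2 scale). Choroid plexus levels were 3.90 and 0.56, and 3.38 and 1.51. These rank alike, though the lists share some members, so choroid plexus as a part of the cause stays open. A later stage stays open. The more mature library of each genotype had a cilia score that differed from its partner's by a mean of -0.598 (SD 0.70 over 3 genotypes), but in floxed genotypes that library also held less choroid plexus. The mature score of floxed libraries exceeded that of wild type by 0.23, less than its pooled SD of 0.36, so no expected difference could be set. More ciliated ventricular wall in the floxed dissections stays open, with 4 of 4 floxed libraries above both wild type ones, because dissection and genotype cannot be told apart. A change of ciliated cells with each floxed allele stays open too, since the step from heterozygous to homozygous was 0.169, after a first step of 2.07, with a pooled SD of 0.58.

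The second pattern is that Rps13 and Rps7 trade level with near-identical copies. For Rps13, reads divided differently among copies may account for it, since the sum of copies varied 1.21-fold while Rps13 alone varied 62.5-fold. For Rps7 and Gm6472 the homozygous sum was 1.36 times that of wild type, and effective lengths that would settle whether reads moved are not in the table. DNA of another strain around Sox11 may play a part on chromosome 12, where 24 of 84 genes within 10 Mb had an unadjusted trend p under 0.01 against 6.42% elsewhere (two-sided Fisher's exact p = 4.3e-10, and 0.00074 for protein-coding genes alone). Fisher's test takes neighbouring genes as independent, and many of the 24 are pseudogenes lying close together, so these p may overstate the excess. Of the 24 genes in that region, 2 rose with more floxed alleles, Cdhr3 and Efcab10, and both count in the protein-coding test. They stood at 0.46 TPM or less in wild type and at 2.57 TPM or more in every floxed library, a rise like that of motile cilia genes. Rps13 on chromosome 7 and its copy on 8 lie outside that region. Gm6472 lies on X, but reads of another strain's Rps7 might align to it, which was not tested, and an effect of the Sox11 allele on its neighbours was not tested.

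The third pattern is the presence of mature brain genes in tissue labelled embryonic day 14. Tissue older than labelled may account for it, since embryonic forms made up at most 0.240% of beta-globin TPM in any library, with adult forms between 35.7 and 151 TPM. Older tissue carried into only some libraries is argued against, since the lowest library still held 0.203 of the highest level for Slc17a7 and more for Gfap and Camk2a. Whether all libraries held older tissue in uneven amounts was not tested. No biological explanation was tested. The labelled age is the same in all groups, but whether the actual age differed between genotypes was not tested. The mature forebrain list stood at -0.21 and 0.21 in wild type and at 0.11 and 0.68 in homozygous libraries, so such a difference stays open.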
